A study of Homo sapiens with 27 samples.

How the data were processed

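RNA was sequenced from 27 samples of MIA PaCa-2, a human pancreatic ductal adenocarcinoma cell line, in which the RNA-binding protein HuR (gene ELAVL1) had been deleted with CRISPR or left intact. The labels put the samples in 8 groups, by genotype (knockout or wild type) and by setting. Cells were collected from culture at 70% confluency, or as tumours 2, 3 and 4 weeks after injection into the pancreas of NRG mice, an immunodeficient strain. Each genotype had 4 cultured samples and 4 week 4 tumours; week 3 had 3 knockout and 4 wild-type tumours, and week 2 had 2 of each. The labels do not say that replicates came from separate cultures or animals, nor how many knockout clones were used, so p-values measure the spread between these samples, which may be technical.

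The submitters' processing notes name CASAVA, bcl2fastq, STAR 2.6.1, HTSeq 0.6.1 and GRCh38.p5, with no roles. Whether counting used strand, and how reads from mouse cells of a tumour were treated, are not given in the sources used here. The authors deposited 4 tables, with knockout and wild type of a setting in each. Per the file headers, each holds raw read counts per gene, which the authors did not normalize. Beside them stand the authors' scaled signal, in which every count of a library is divided by the same size factor, and deposited FPKM values, scaled to gene length and to the counted reads of the library. The authors also deposited a log2 fold change, a p-value and an adjusted p-value per gene, with the tool not given in the sources used here. A gene with no read in any library of a table is not listed in it and was counted as 0 when tables were joined. The joined tables hold 29263 genes, and 113 gene symbols belong to more than 1 gene. Gene coordinates in the tables differ from GRCh38 and are not printed. The position of ELAVL1 and the order of genes along chromosomes come from GENCODE release 29 on GRCh38.

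The raw counts were the input of every test below. Totals ran from 23880372 to 37428467 counted reads per library, a 1.57-fold range, and 16497 to 20355 genes had at least 1 read. For each setting, edgeR 4.0.16 in R 4.3.3 compared knockout with wild type, with filterByExpr, TMM scaling and robust quasi-likelihood fits, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Every adjusted p for a gene given below is from edgeR unless another tool is named. Means are TMM-scaled CPM with the SD between libraries. Differences between knockout effects, and wild-type tumours against wild-type culture, were tested in a joint edgeR fit of all 27 libraries with group means, which shares an estimate of the spread. Fitted fold changes use the default prior count of edgeR, and the log2 CPM of the list tests a prior count of 2. Where a group had no reads, the fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads in a group, the ratio of summed reads scaled to library size is given with a 95% exact interval, which like the floor covers counting error only.

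Before the data were examined, 30 gene lists were fixed. The 22 program lists are reported HuR target mRNAs, ELAVL and other AU-rich element binding proteins, mitosis, DNA replication, homologous recombination repair, mesenchymal, epithelial, hypoxia response, glycolysis, oxidative phosphorylation, interferon response, MHC class I presentation, NF-kB and cytokine, AP-1 and immediate early, ATF4 and amino acid stress response, endoplasmic reticulum chaperones, cholesterol synthesis, p53 target, apoptosis regulators, MAPK feedback, integrins and focal adhesion, and ribosomal proteins. A list of mitochondrially encoded genes served as a sign of RNA quality, and 7 lists mark other cell types: fibroblast and pericyte, endothelial, myeloid, pancreatic acinar, pancreatic islet, erythroid and adipocyte. Of 636 list genes, 31 were not matched by symbol. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members past the threshold were counted over all genes tested and with p-values adjusted over the list alone.

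The rule for named genes was fixed with the lists. It takes ELAVL1; per comparison the 8 largest rises and 8 largest falls among called protein-coding genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups; and up to 3 called members of each list with the smallest adjusted p, or up to 2 as values where none was called. For genes called in all 4 comparisons, and for each test of the joint fit, it takes 5 per direction. Some genes the rule takes are not reported here. Overlaps of calls used Fisher's exact test, and the 4 comparisons share no libraries.

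Scripts were tested on simulated negative binomial counts, drawn from the gene means over all libraries of a comparison, the gene-wise dispersions and the library sizes, with 100 genes changed 2-fold, 100 changed 1.5-fold and, for the list test, 30 more raised 1.5-fold. Of the 2-fold changes, 73 were recovered in culture (14564 genes), 30 at week 2 (14987 genes), 26 at week 3 (14638 genes) and 71 at week 4 (14437 genes). Of the 1.5-fold changes, 61, 2, 0 and 54 were recovered in the same order. For the difference between the week 4 and week 3 effects (17925 genes), 18 and 5 were recovered. In each comparison of knockout with wild type, far fewer genes changed in the simulation than were called in the data. This makes the adjusted threshold stricter, so these counts are not the power of the real comparisons. False calls in the simulation were 8 of 156 calls in culture, 5 of 37 at week 2, 0 of 26 at week 3 and 8 of 143 at week 4. All 35 pairs of replicates differed by more than sampling noise, with chi-square per degree of freedom from 11.2 to 290, so no library was counted as a copy of another. Alternatives were DESeq2 1.42.0, RLE size factors, other filters on low counts, a stricter threshold of 2-fold, the replicate number as a block, a joint fit, leaving out genes of other cell types or each library in turn, and fry for lists. Genes that share reads with close copies, such as SULT1A1, KLRC2, HSPA6 and the APOBEC3 genes are uncertain, as are antisense genes.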

Results

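ELAVL1, the deleted gene, kept a reduced level of mRNA in every knockout group. In culture, ELAVL1 stood at 98.6 ± 3.89 CPM in knockout cells against 227 ± 18.6 CPM in wild type (SD, n = 4 and 4; log2 fold change -1.20, SE 0.07, adjusted p = 1.1e-09). The tumours gave 94.2 ± 9.08 against 170 ± 16.7 CPM at week 2 (n = 2 and 2; log2 -0.85, SE 0.16, adjusted p = 0.0084), 84.5 ± 8.36 against 160 ± 11.5 CPM at week 3 (n = 3 and 4; log2 -0.92, SE 0.14, adjusted p = 0.0012) and 82.1 ± 1.33 against 159 ± 9.03 CPM at week 4 (n = 4 and 4; log2 -0.95, SE 0.07, adjusted p = 3.4e-09). By library, unscaled CPM ran from 76.2 to 103 in knockouts and from 140 to 234 in wild type, with no overlap. The log2 fold changes in the authors' table are -1.18, -0.83, -0.91 and -0.95. Without WT_week2 replicate 3 the week 2 value is -0.75 and the call of ELAVL1 ends (adjusted p = 0.0592). The gene lies on the minus strand of chromosome 19 at 7958579 to 8005659, and counts per gene do not show whether the remaining transcripts carry the deletion.

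**Figure D1:**
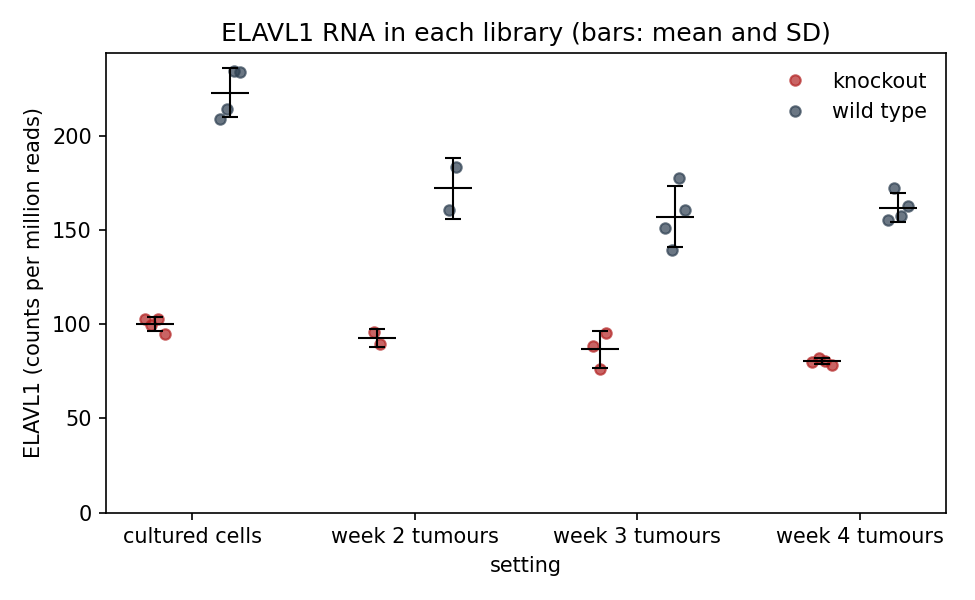
ELAVL1 in CPM without TMM scaling (vertical axis) by setting (horizontal axis), in knockouts (red) and wild type (dark blue). Each point is a library and the bars are means with the SD, with 100 ± 3.75 CPM in cultured knockout cells and 223 ± 13.1 CPM in cultured wild type.

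Setting and genotype both part the libraries. Over 12985 genes, the first 4 principal components hold 41.5%, 23.9%, 7.83% and 5.31% of the variance. WT_week3 replicate 2 lies apart on the fourth component, with a score of 61.8.

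**Figure D2:**
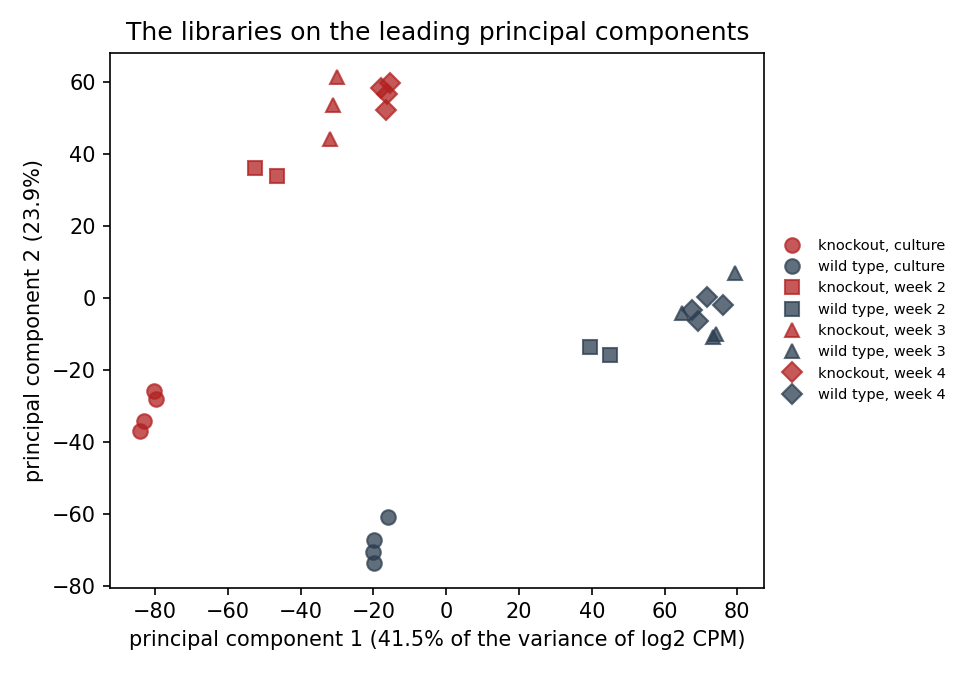
Scores of the 27 libraries on the first component of log2 CPM (horizontal axis, 41.5% of the variance) and the second (vertical axis, 23.9%). Each point is a library, with colour for genotype (knockout red, wild type dark blue) and shape for setting.

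In culture, knockout cells gained high levels of several genes that wild type barely expressed. ZNF608, a zinc finger gene, stood at 116 ± 4.59 against 1.17 ± 0.186 CPM (log2 6.62, adjusted p = 6.9e-17), LAPTM5, a lysosomal membrane protein best known from blood cells, at 157 ± 19.2 against 3.18 ± 0.769 CPM, and F2RL2, a thrombin receptor, at 50.7 ± 4.18 against 0.746 ± 0.348 CPM (SD, n = 4 and 4). KLK5, a secreted serine protease, and SFRP1, a secreted Wnt antagonist, rose as well (log2 4.87 and 4.48). So did CX3CL1, a chemokine, APOBEC3G, a cytidine deaminase, and CORO2B (log2 5.02, 4.45 and 5.37). PTX3, a secreted pattern recognition protein, fell from 3619 reads in wild type to 1 read in knockouts, a ratio of 4013 (interval 720 to 158560). PNMAL1 had 2 against 1496 reads (ratio 829, 229 to 6856) and ZNF558 3 against 1819 reads (ratio 672, 230 to 3264). EFNA5, an ephrin ligand, COL3A1, a fibrillar collagen, INPP4B, a lipid phosphatase, FAM198B and PTPRZ1, a receptor phosphatase, fell from 13.8 to 24.6 CPM to at most 0.116 ± 0.0912 CPM (log2 -8.76, -8.21, -8.20, -7.93 and -7.62). In edgeR, 5737 of 14803 tested genes were called, 2560 higher and 3177 lower in knockouts, and 1503 of them changed at least 2-fold (501 higher, 1002 lower).

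Among the fixed lists, MAPK feedback genes rose in cultured knockout cells. Of 22 tested, 13 rose and 0 fell by edgeR (14 and 0 adjusted over the list alone; camera adjusted p = 2.2e-04), with a median log2 of 0.43; adjusted p = 0.319 with an estimated correlation. DUSP6, a phosphatase that acts on ERK, went to 30.7 ± 4.06 against 5.91 ± 2.11 CPM (log2 2.37, adjusted p = 2.9e-07), ETV4, an ETS transcription factor, to 58.4 ± 3.33 against 25.4 ± 1.54 CPM (log2 1.20, adjusted p = 3.1e-09), and IER3 to 24.9 ± 3.13 against 11.4 ± 1.06 CPM. Of 21 genes of the ATF4 and amino acid stress response, 10 rose and 2 fell, also when adjusted over the list alone (median 0.36, camera adjusted p = 0.0272; adjusted p = 0.970 with an estimated correlation). That call ends without KO_cell_line replicate 3 (adjusted p = 0.071) or without KO_cell_line replicate 4 (adjusted p = 0.065). Its members CEBPB (75.4 ± 9.13 against 37.9 ± 2.35 CPM) and TRIB3 (60.2 ± 8.78 against 34 ± 4.03 CPM) rose. The reported HuR target mRNAs went both ways: 11 of 33 rose and 8 fell, the same adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.494). BCL2 (3.38 ± 0.282 against 10.6 ± 1.45 CPM, log2 -1.65) and IL8 (28.2 ± 4.78 against 54.9 ± 5.64 CPM, log2 -0.96) fell, and CDKN1A, an inhibitor of the cell cycle, rose (6.8 ± 0.847 against 1.95 ± 0.505 CPM, log2 1.79). For ELAVL and other AU-rich element binding proteins, 4 of 17 rose and 6 fell (camera adjusted p = 0.950), with a median of -0.02, a mean of 0.16 and a downward test. Of 21 p53 target genes 9 rose and 3 fell (camera adjusted p = 0.0971), with FAS, a death receptor, at 35.1 ± 5.2 against 8.65 ± 0.392 CPM and GDF15 at 7 ± 1.58 against 0.561 ± 0.242 CPM. AP-1 and immediate early genes gave 4 up and 4 down of 17 (camera adjusted p = 0.753; median -0.17, mean 0.17, upward test), with FOSL2 at 251 ± 20 against 95.3 ± 16.1 CPM. Apoptosis regulators gave 2 up and 5 down of 21 (camera adjusted p = 0.845; median 0.13, mean -0.06, upward test). The cell junction genes CLDN1 (2.59 ± 0.854 against 30.3 ± 1.64 CPM, log2 -3.56) and DSP (5.75 ± 1.9 against 57.8 ± 6.43 CPM, log2 -3.33) and the matrix protein TGFBI (0.456 ± 0.0587 against 18.7 ± 1.07 CPM, log2 -5.34) fell. The glucose transporter SLC2A3 (149 ± 30.1 against 14.9 ± 3.37 CPM, log2 3.31) and the replication factor GINS4 (216 ± 15.5 against 48.3 ± 2.18 CPM, log2 2.16) rose.

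In week 2 tumours, LAPTM5, ZNF608 and F2RL2 were again high in knockouts, beside secreted kallikrein proteases. LAPTM5 stood at 257 ± 21.3 against 4.52 ± 1.45 CPM (adjusted p = 3.7e-06), ZNF608 at 104 ± 14 against 1.58 ± 0.0689 CPM and F2RL2 at 41.6 ± 18.4 against 0.292 ± 0.413 CPM (SD, n = 2 and 2). KLK7 rose to 181 ± 34 against 4 ± 1.7 CPM, SNCG, a synuclein, to 191 ± 53.2 against 2.85 ± 1.21 CPM and KLK10 to 13.4 ± 3.51 against 0.109 ± 0.106 CPM. CPA5, a carboxypeptidase, had 637 reads in knockouts and 0 in wild type, at least 248-fold. PTX3 had no knockout read against 126 ± 24.3 CPM in wild type, at least 2241-fold lower. FAM198B (42.4 ± 3.9 CPM in wild type, at least 751-fold), KRT5 (at least 228-fold), VAV3 (at least 214-fold), EMC10 (at least 211-fold), COL13A1 (at least 196-fold) and ZNF471 (at least 195-fold) also had no knockout read, and PDLIM1 fell to 0.123 ± 0.174 against 167 ± 48.3 CPM (log2 -10.46). By edgeR 2039 of 15811 genes were called, 822 higher and 1217 lower, and 1260 changed at least 2-fold (493 higher, 767 lower). At this group size the simulation, in which far fewer genes changed than were called here, recovered 2 of 100 changes of 1.5-fold.

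Called members of the immune, adhesion and cell division lists mostly fell at week 2, and those of the mitochondrially encoded and ribosomal protein lists rose. Of 22 NF-kB and cytokine genes 8 fell and 0 rose (16 fell adjusted over the list alone; median -1.26, camera adjusted p = 2.3e-06; adjusted p = 0.806 with an estimated correlation). TNFAIP2 went to 61.9 ± 0.921 against 419 ± 2.31 CPM (log2 -2.76, adjusted p = 8.8e-06), and NFKBIA, the inhibitor of NF-kB, to 58.8 ± 11.8 against 201 ± 3.74 CPM. Of 21 integrins and focal adhesion genes 12 fell and 0 rose (16 adjusted over the list alone; median -1.05, camera adjusted p = 3.4e-06; adjusted p = 0.806 with an estimated correlation), among them CAV1 (165 ± 53.9 against 581 ± 35.1 CPM) and ZYX (53.8 ± 3.17 against 159 ± 14.3 CPM). Of 31 interferon response genes 12 fell and 2 rose (17 and 3 adjusted over the list alone; median -0.81, camera adjusted p = 8.3e-04). ISG15, a ubiquitin-like protein, went to 24 ± 0.698 against 104 ± 13.6 CPM (log2 -2.12, adjusted p = 1.2e-04), and OASL to 15.8 ± 4.6 against 114 ± 39.3 CPM. Of 28 mitosis genes 10 fell and 0 rose (16 adjusted over the list alone; median -0.52, camera adjusted p = 3.4e-05), with MKI67 at 239 ± 14.1 against 427 ± 22.5 CPM. Of 14 epithelial genes 7 fell and 2 rose (8 and 2 adjusted over the list alone; median -1.59, camera adjusted p = 6.0e-04), with KRT18 at 451 ± 111 against 1793 ± 38.5 CPM. Of 21 cholesterol synthesis genes 9 fell and 0 rose (13 adjusted over the list alone; median -0.82, camera adjusted p = 7.1e-04). Of 13 mitochondrially encoded genes 12 rose and 0 fell, also adjusted over the list alone (median 1.16, camera adjusted p = 2.6e-07), with MT-CO1 at 30242 ± 5743 against 11540 ± 224 CPM. Of 30 ribosomal proteins 9 rose and 0 fell (19 adjusted over the list alone; median 0.38, camera adjusted p = 3.3e-05), with RPL38 at 221 ± 22 against 122 ± 3.56 CPM. Mitochondrial reads were 10.1% and 8.74% of the knockout libraries and 4.09% and 4.06% of the wild-type libraries. The calls of MT-CO1, MT-CYB and MT-ND1 end in a joint fit of all libraries. Each of the lists from interferon response on, and those of the next paragraph, had adjusted p = 0.841 with an estimated correlation.

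A further 5 lists called at week 2 rest on single libraries. Of 30 oxidative phosphorylation genes 3 rose and 0 fell, the same adjusted over the list alone (median 0.37, camera adjusted p = 0.0022; 0.057 without KO_week2 replicate 3). Of 30 DNA replication genes 4 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.39, camera adjusted p = 0.0034; 0.102 without KO_week2 replicate 1, 0.074 without WT_week2 replicate 3). For the reported HuR target mRNAs 7 of 33 fell and 1 rose, the same adjusted over the list alone (median -0.28, camera adjusted p = 0.0254; 0.051 without KO_week2 replicate 1, 0.148 without WT_week2 replicate 3). PLAU, a protease that activates plasminogen, fell (51.8 ± 11.1 against 293 ± 35.7 CPM, log2 -2.50), MYC fell (147 ± 4.72 against 292 ± 2.28 CPM, log2 -0.99) and HDAC1 rose (408 ± 3.32 against 190 ± 12.8 CPM, log2 1.10). Of 18 endoplasmic reticulum chaperones 2 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.36, camera adjusted p = 0.0280; 0.392 without KO_week2 replicate 3, 0.074 without WT_week2 replicate 3). Of 20 genes of homologous recombination repair 1 fell and 0 rose, the same adjusted over the list alone (median -0.35, camera adjusted p = 0.0464; 0.36 without KO_week2 replicate 1, 0.326 without WT_week2 replicate 3).

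**Figure D3:**
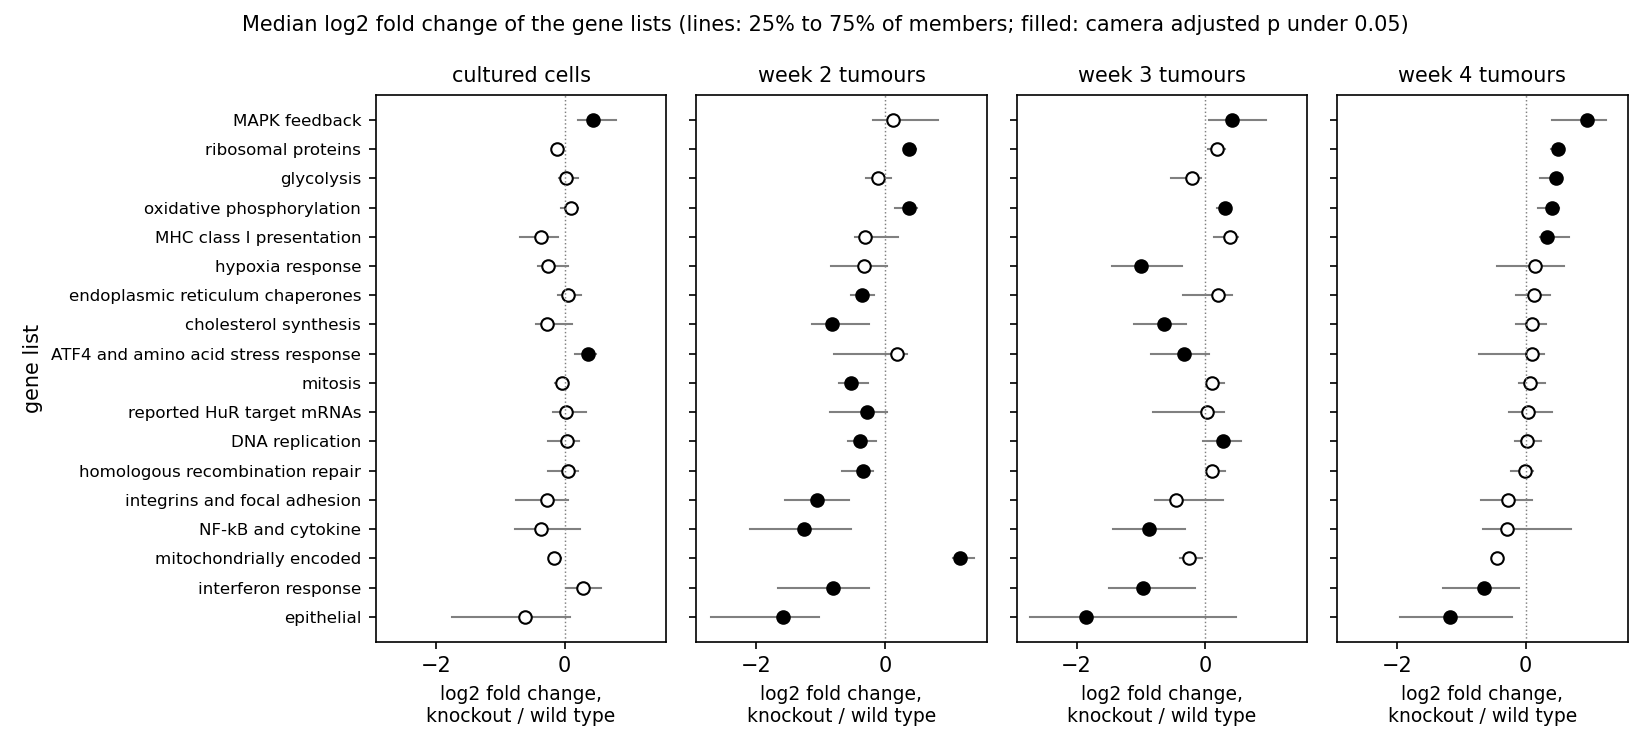
Log2 fold change of knockout over wild type (horizontal axis) for the gene lists called in any setting (vertical axis), with a panel per setting. Points are medians over the members of a list, filled where camera called it, and lines span the middle 50% of members, with MAPK feedback medians of 0.43 in culture and 0.96 at week 4.

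In week 3 tumours, PTX3 was far lower in knockouts and several kallikreins far higher, and more hypoxia and interferon genes fell than rose. PTX3 had 49437 reads in wild type (436 ± 49.5 CPM) and 0 in knockouts, at least 12682-fold lower. ADM, the vasodilator adrenomedullin, fell to 7.72 ± 0.974 against 129 ± 19.2 CPM (log2 -4.06, adjusted p = 1.4e-06), and VEGFA, the main angiogenic growth factor, to 54.1 ± 9.16 against 254 ± 46.7 CPM (log2 -2.23, adjusted p = 4.9e-05), as means with the SD (n = 3 and 4). KLK10 rose to 69.4 ± 29.5 against 0.0875 ± 0.111 CPM (log2 9.54, adjusted p = 5.5e-06), KLK7 to 174 ± 15.5 against 1.54 ± 0.785 CPM, KLK13 to 14.1 ± 4.56 CPM and LAPTM5 to 697 ± 261 against 4.94 ± 0.842 CPM (log2 7.14, adjusted p = 8.6e-07). F2RL2, ZNF608, CPA4 and SULT1A1 were also among the largest rises (log2 7.18, 6.92, 6.92 and 6.43). Of the other large falls, DENND2A (30.9 ± 16.4 CPM in wild type, at least 897-fold) and COL3A1 (12 ± 3.02 CPM in wild type, at least 339-fold) had no knockout read, TPD52L1 and EMC10 had 1 (ratios of 2590, 464 to 102318, and 1602, 287 to 63288), and CDH5, the cadherin of endothelial junctions, fell to 0.556 ± 0.523 against 206 ± 61.7 CPM (log2 -8.58). PNMAL1 and ATP8B1 fell as well (log2 -8.35 and -8.16). By edgeR 3268 of 15286 genes were called, 1430 higher and 1838 lower, and 1945 changed at least 2-fold (756 higher, 1189 lower). Leaving out KO_week3 replicate 4 gives 1925 calls and leaving out WT_week3 replicate 2 gives 5460. WT_week3 replicate 2 has 8.84% mitochondrial reads, against 1.44% to 3.60% in the other week 3 libraries of wild type.

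Of 24 hypoxia response genes, 15 fell and 1 rose in week 3 knockout tumours, also adjusted over the list alone (median -1.01, camera adjusted p = 1.0e-04; adjusted p = 0.587 with an estimated correlation). HILPDA, a lipid droplet protein, went to 10.8 ± 2.93 against 62 ± 11.9 CPM. Of 33 interferon response genes 18 fell and 3 rose (19 and 4 adjusted over the list alone; median -0.97, camera adjusted p = 0.0011; adjusted p = 0.614 with an estimated correlation). RSAD2, the antiviral protein viperin, fell to 4.26 ± 1.53 against 54.7 ± 9.74 CPM (log2 -3.69, adjusted p = 1.6e-05), and IFIT3 to 127 ± 23.2 against 449 ± 43.7 CPM. Of 24 NF-kB and cytokine genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.88, camera adjusted p = 0.0061; adjusted p = 0.704 with an estimated correlation), with BIRC3 at 88.7 ± 54.3 against 434 ± 169 CPM. Of 21 cholesterol synthesis genes 9 fell and 0 rose (11 adjusted over the list alone; median -0.64, camera adjusted p = 0.0016; adjusted p = 0.587 with an estimated correlation), with DHCR7 at 56.6 ± 18.4 against 202 ± 35.9 CPM. Of 14 epithelial genes 8 fell and 2 rose (9 and 3 adjusted over the list alone; median -1.86, camera adjusted p = 0.0063; adjusted p = 0.560 with an estimated correlation): CLDN1 fell (32 ± 12.4 against 375 ± 102 CPM, log2 -3.55) and the keratin KRT19 rose (1088 ± 56.3 against 120 ± 44.1 CPM, log2 3.18). The other 4 calls depend on single libraries. Oxidative phosphorylation had 4 up and 0 down of 30 (3 up adjusted over the list alone; camera adjusted p = 0.0083, 0.064 without WT_week3 replicate 1; adjusted p = 0.704 with an estimated correlation). DNA replication had 8 up and 1 down of 30 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0248, 0.05 without KO_week3 replicate 4, 0.068 without WT_week3 replicate 1; adjusted p = 0.629 with an estimated correlation). MAPK feedback had 8 up and 1 down of 22, the same adjusted over the list alone (camera adjusted p = 0.0248, 0.164 without KO_week3 replicate 2, 0.058 without WT_week3 replicate 2; adjusted p = 0.629 with an estimated correlation). The ATF4 and amino acid stress response had 1 up and 6 down of 21, the same adjusted over the list alone (camera adjusted p = 0.0342). The camera adjusted p is 0.076 without KO_week3 replicate 1, 0.065 without WT_week3 replicate 2, 0.0571 with the replicate block and 0.587 with an estimated correlation. ATF3 of this list was at 4.68 ± 0.727 against 36.9 ± 4.62 CPM and ASNS, asparagine synthetase, at 19.1 ± 1.5 against 65.5 ± 7.94 CPM.

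In week 4 tumours, LAPTM5 reached 1087 ± 79.9 against 13.7 ± 7.03 CPM and KLK10 132 ± 22.8 against 0.497 ± 0.318 CPM (log2 8.05, adjusted p = 2.0e-09), while PTX3 stayed at 0.151 ± 0.108 against 281 ± 76.5 CPM (log2 -10.82, adjusted p = 2.3e-09; SD, n = 4 and 4). KLK13 had 2636 reads against 2 (ratio 1358, 376 to 11220) and NOX3, an NADPH oxidase, 1275 against 1 (ratio 1314, 235 to 51931). SNCG rose to 184 ± 16 against 0.94 ± 1.12 CPM, PLCXD3 to 55.5 ± 10 against 0.49 ± 0.222 CPM, APOBEC3H to 18.7 ± 1.5 CPM and CPA4 to 18 ± 10.1 CPM. TNC, the matrix protein tenascin C, rose with a wide spread (20.6 ± 24.1 against 0.176 ± 0.122 CPM, log2 6.85, adjusted p = 0.0043). PNMAL1 (23.8 ± 1.6 CPM in wild type, at least 843-fold) and ZNF347 (at least 356-fold) had no knockout read, DENND2A had 1 (ratio 3072, 551 to 121361), and BCHE, butyrylcholinesterase, and EMC10 had 2 each (ratios of 1197, 331 to 9890, and 985, 272 to 8139). MAP1B and TPD52L1 fell from 23.4 ± 5.13 and 21.7 ± 2.68 CPM (log2 -9.12 and -8.48). By edgeR 6536 of 14761 genes were called, 3186 higher and 3350 lower, and 2026 changed at least 2-fold (794 higher, 1232 lower).

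Most genes of the MAPK feedback, energy and ribosomal protein lists rose at week 4, and more interferon genes fell than rose. Of 30 ribosomal proteins 25 rose and 0 fell (27 adjusted over the list alone; median 0.50, camera adjusted p = 1.1e-06), with RPL22 at 425 ± 29.5 against 224 ± 25.8 CPM (log2 0.93, adjusted p = 6.2e-08). Of 30 oxidative phosphorylation genes 19 rose and 1 fell (20 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 3.1e-04), with UQCRC1 at 272 ± 24.4 against 159 ± 16.6 CPM. Of 18 glycolysis genes 14 rose and 1 fell, the same adjusted over the list alone (median 0.47, camera adjusted p = 6.9e-04). The glucose transporter SLC2A1 went to 392 ± 21.2 against 149 ± 21.8 CPM (log2 1.40, adjusted p = 3.7e-10), and pyruvate kinase PKM to 3257 ± 144 against 2018 ± 70 CPM. Of 13 genes of MHC class I presentation 9 rose and 0 fell, the same adjusted over the list alone (median 0.33, camera adjusted p = 0.0063). Of 31 interferon response genes 18 fell and 4 rose (19 and 4 adjusted over the list alone; median -0.65, camera adjusted p = 9.4e-04), with PARP9 at 26.3 ± 1.82 against 74.5 ± 5.36 CPM (log2 -1.50, adjusted p = 1.6e-10), and OAS2, which makes an antiviral second messenger, at 41.6 ± 7.3 against 132 ± 10.8 CPM. These 5 lists had adjusted p = 0.784 with an estimated correlation. Of 22 MAPK feedback genes 16 rose and 1 fell, the same adjusted over the list alone (median 0.96, camera adjusted p = 7.3e-06; adjusted p = 0.397 with an estimated correlation). The EGFR ligand EREG went to 936 ± 128 against 388 ± 36.7 CPM and the receptor EPHA2 to 535 ± 36.3 against 228 ± 26.7 CPM. Of 14 epithelial genes 9 fell and 3 rose, the same adjusted over the list alone (median -1.17, camera adjusted p = 0.0174; adjusted p = 0.696 with an estimated correlation): DSP fell (10.7 ± 1.17 against 110 ± 11.3 CPM, log2 -3.36) and CLDN4 rose (261 ± 35.1 against 71 ± 5.3 CPM, log2 1.88). Mesenchymal genes gave 6 up and 3 down of 16 (camera adjusted p = 0.534), with TGFBI falling to 6.21 ± 2.33 against 68.1 ± 3.69 CPM. Of 24 hypoxia response genes 8 rose and 6 fell (camera adjusted p = 0.534): the glucose transporter SLC2A3 rose to 386 ± 29.7 against 31.2 ± 3.55 CPM (log2 3.63, adjusted p = 6.8e-16), and ADM fell to 15.6 ± 1.13 against 59.7 ± 10.2 CPM.

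Markers of other cell types moved in part at weeks 2, 3 and 4, and camera called no such list between knockout and wild type. At week 2, with 2 libraries per group, the pancreatic islet sum was 42.4 ± 3.68 against 136 ± 26.2 unscaled CPM. The endothelial sum was 161 ± 45.5 against 256 ± 11.7 CPM, and neither list overlapped between genotypes. Sums of the myeloid, pancreatic acinar and adipocyte lists were higher in knockouts without overlap, and those of the other lists overlapped. LAPTM5 alone gave 253 of the 267 CPM of the myeloid list in week 2 knockouts, and the list without it summed to 13.7 against 8.38 CPM. The adipocyte sums were 36.9 against 30.1 CPM at week 2 and 37.9 against 32.7 CPM in culture, which holds only the cell line. With 2 libraries per group, sums often part without overlap by chance. At week 3 the fibroblast and pericyte list summed to 2161 ± 302 unscaled CPM in knockouts against 1105 ± 330 in wild type, with no overlap, mostly from COL1A2 (1367 ± 323 against 536 ± 209 CPM, log2 1.35). In culture, which holds only the cell line, the list summed to 1449 ± 236 against 1306 ± 89 unscaled CPM. These sums therefore do not by themselves show fibroblasts. Of the 12 genes of the list tested at week 3, 5 rose and 3 fell (camera adjusted p = 0.579; median 0.40, mean -0.61, upward test). The pancreatic islet list summed to 65.9 ± 24.8 against 241 ± 98.4 unscaled CPM, mostly from SCG2 (43.7 ± 23 against 225 ± 94.4 CPM), and 1 of its 3 genes rose and 1 fell (camera adjusted p = 0.724). COL1A2 and SCG2 were chosen after their values were seen. Of 7 myeloid genes 2 rose and 0 fell at week 3 (median 1.81, camera adjusted p = 0.0580; adjusted p = 0.601 with an estimated correlation), though fry calls the list (adjusted p = 0.0023). The list without LAPTM5 summed to 19.4 to 34.4 unscaled CPM in knockouts against 11.2 to 16.3 in wild type. Of 3 pancreatic acinar genes 1 rose and 0 fell (median 1.09, camera adjusted p = 0.0580; adjusted p = 0.587 with an estimated correlation; fry adjusted p = 7.8e-04), with sums of 6.42 to 10.98 against 1.05 to 3.59 unscaled CPM. Against culture, the knockout effect at week 3 was more positive for both lists (camera adjusted p = 0.0344 and 0.0462; 0.193 and 0.332 with an estimated correlation). At week 4, of 7 myeloid genes 3 rose and 2 fell (camera adjusted p = 0.534; fry adjusted p = 0.0087, up). LAPTM5 was 143 to 187 CPM in cultured knockout cells and at most 21.2 CPM in any wild-type library. Of 7 endothelial genes 2 rose and 2 fell (camera adjusted p = 0.896; fry adjusted p = 0.0114, down). CDH5 was 49.8 to 274 CPM in wild-type tumours and at most 1.92 CPM in knockout tumours, and in culture it was 3.02 to 7.03 CPM in wild type with no read in knockouts. Of 15 fibroblast and pericyte genes 5 rose and 3 fell (camera adjusted p = 0.708; median -0.16, mean -0.04, upward test), with COL6A3, a collagen VI chain, rising to 256 ± 33.7 against 72.9 ± 11.9 CPM. Of 3 pancreatic islet genes 1 rose and 1 fell (camera adjusted p = 0.548; fry adjusted p = 3.2e-04, down). By fry the endothelial list is also called down at week 3 (adjusted p = 0.0226), and in culture the myeloid list up (4.8e-07) and the endothelial (0.0287) and islet (0.0176) lists down. At week 4 the pancreatic acinar list had 2 tested genes, which both rose, the adipocyte list 2, of which 1 rose, and the erythroid list 1, which was not called. Lists with fewer than 3 tested genes were not tested.

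Many genes changed the same way in all 4 settings. Of 13785 genes tested in each, 288 were higher and 593 lower in knockouts throughout, against 3.11 and 7.38 if the comparisons were independent. A lasting difference between knockout and wild-type cells, of whatever cause, would recur in each setting, so these are not 4 separate tests of HuR. The overlap test below also takes genes as independent, which neighbouring genes that move together are not. F2RL2 (log2 6.04, 7.08, 7.18 and 6.63 from culture to week 4) and ZNF608 (log2 6.62, 6.04, 6.92 and 5.65) were among the largest shared rises, with the long noncoding RNA RP11-71N10.1, which had no wild-type read (at least 75.4-fold, 129-fold, 112-fold and 59.8-fold), and TBC1D8B, which had at most 1 wild-type read per setting against 73 to 227 in knockouts. PTX3, PNMAL1, ZNF471, CDH10, a cadherin, and the long noncoding RNA GS1-600G8.5 (log2 -7.82, -8.86, -9.41 and -7.88) led the shared falls. ZNF471 (at least 106-fold, 195-fold, 234-fold and 241-fold) and CDH10 (at least 224-fold, 46.5-fold, 46.7-fold and 110-fold) had no knockout read in any setting. In the 3 tumour comparisons, 385 genes were higher and 750 lower throughout. Fold changes of week 3 and week 4 tumours had a Spearman correlation of 0.702, those of culture and week 2 one of 0.478. Culture and week 2 shared 454 rises (142 if independent; Fisher's exact test, adjusted p = 2.4e-146) and 853 falls (257 if independent). Between any pair of settings, 477 genes were called in opposite directions.

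Some knockout effects differed between culture and tumour, as tested in the joint edgeR fit of 18792 genes. CORO2B, an actin binding protein, was 17.2 ± 1.9 CPM in knockout and 0.407 ± 0.191 CPM in wild-type culture, but 3.01 ± 0.801 and 40.6 ± 10.8 CPM in week 3 tumours (SD; difference of log2 effects -9.14, SE 0.41, adjusted p = 4.6e-16). IGFBP4, a binding protein of insulin-like growth factors, was 211 ± 18.8 against 270 ± 48 CPM in culture and 852 ± 107 against 18.1 ± 6.92 CPM at week 3 (difference 5.92, SE 0.41, adjusted p = 1.1e-09). TNS4, a focal adhesion protein, was 3.97 ± 1.23 against 7.66 ± 0.7 CPM in culture and 26.9 ± 3.73 against 0.311 ± 0.0845 CPM at week 3. PPAP2B, a lipid phosphatase, turned from 2.23 ± 0.401 against 15.4 ± 1.19 CPM in culture to 57.9 ± 11 against 5.96 ± 1.76 CPM at week 4 (difference 6.06, adjusted p = 1.1e-06). Relative to culture, the effect differed for 741 genes at week 2 (233 more positive, 508 more negative), 2484 at week 3 (1146 and 1338) and 1741 at week 4 (927 and 814). The week 2 count is 376 without WT_week2 replicate 3. With only the groups of the contrast the counts are 2142 (948 and 1194), 2170 (1030 and 1140) and 3509 (1950 and 1559). Of 33 interferon response genes, 15, 16 and 14 had a more negative effect at weeks 2, 3 and 4 than in culture, and 0 a more positive one. The medians were -1.11, -0.96 and -0.79 (camera adjusted p = 5.8e-11, 2.7e-07 and 2.1e-07). Their adjusted p = 0.263, 0.332 and 0.412 with an estimated correlation.

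**Figure D4:**
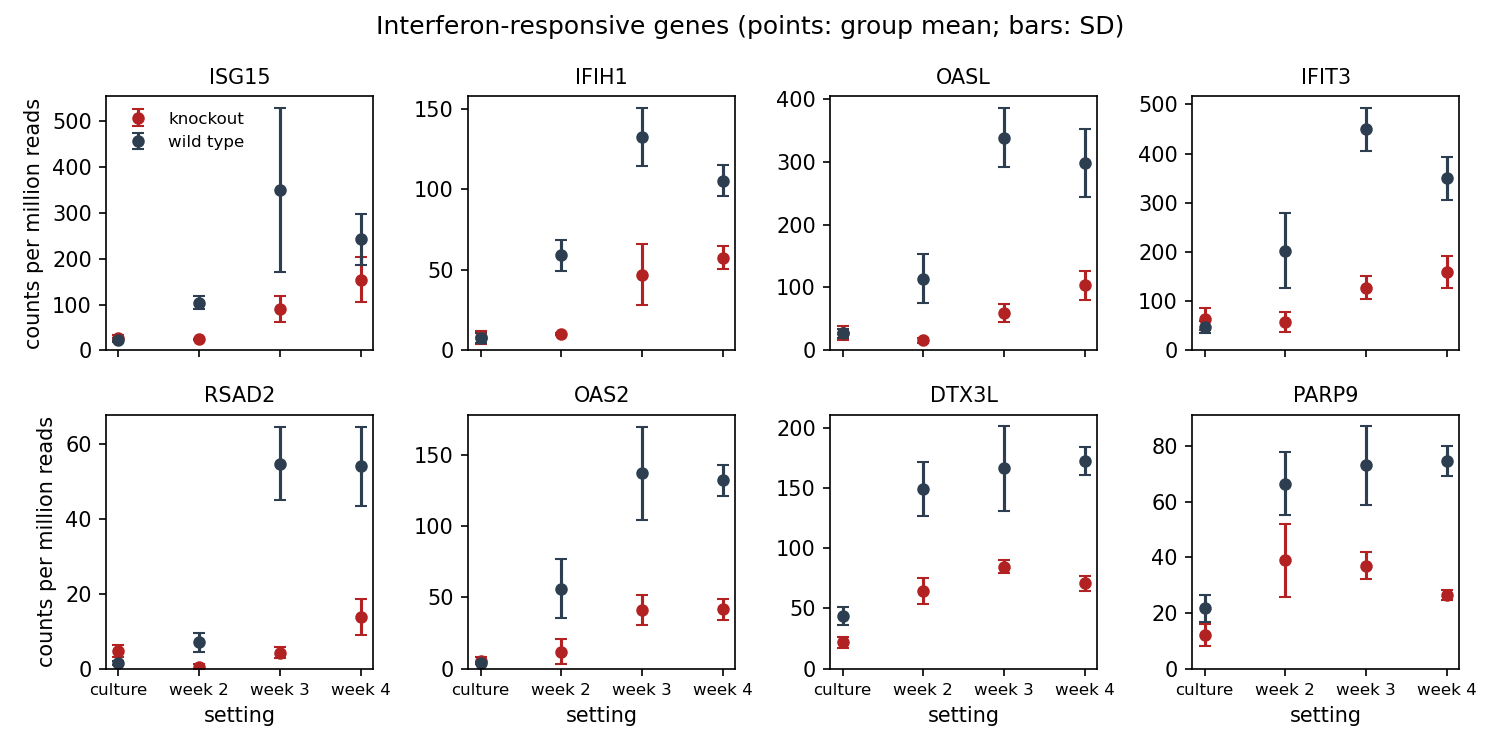
CPM (vertical axis) of 8 interferon response genes by setting (horizontal axis), in knockouts (red) and wild type (dark blue). The 8 are a selection and do not stand for the whole list, whose counts are in the text. XAF1 of the list, not drawn, was higher in knockouts at week 3 (31 ± 8.66 against 12.1 ± 0.727 CPM). Points are group means and bars the SD, with RSAD2 at 4.26 ± 1.53 against 54.7 ± 9.74 CPM at week 3.

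Between tumour ages, the hypoxia and glycolysis genes past the threshold had a more positive knockout effect at week 4 than at week 3. Of 24 hypoxia response genes 15 were more positive and 0 more negative (median 1.29, camera adjusted p = 2.6e-18; adjusted p = 0.0739 with an estimated correlation). Of 18 glycolysis genes 8 were more positive and 0 more negative (median 0.71, camera adjusted p = 1.6e-11; adjusted p = 0.129 with an estimated correlation). HSPA6, a heat shock protein, was 1.73 ± 0.998 against 5.99 ± 1.14 CPM at week 3 and 12 ± 7.02 against 3.23 ± 0.733 CPM at week 4 (difference 3.69, SE 0.69, adjusted p = 0.0025). ABCG1, a sterol transporter, was 10.4 ± 3.86 against 0.628 ± 0.465 CPM and then 4.11 ± 1.2 against 2.27 ± 1.08 CPM (difference -3.21, SE 0.59, adjusted p = 0.0019). Mesenchymal genes had 1 more positive and 1 more negative of 17 (median 0.55, camera adjusted p = 0.0015; 0.0293 with an estimated correlation). In all, 397 genes differed between weeks 4 and 3 (318 more positive, 79 more negative), 686 between weeks 3 and 2 (385 and 301) and 810 between weeks 4 and 2 (542 and 268). MATN2, a matrix protein, was 28.3 ± 6.85 against 83.6 ± 20.9 CPM at week 2 and 10.4 ± 1.69 against 186 ± 21.9 CPM at week 4 (difference -2.60, SE 0.30, adjusted p = 3.6e-06). The counts depend on which libraries are fitted. With only the libraries of the contrast, 9 genes differ between weeks 3 and 2, 192 between weeks 4 and 3 and 1189 between weeks 4 and 2. That fit changes the filter, the scaling and the spread together. Single libraries move them too. Between weeks 4 and 3, counts are 238 without KO_week3 replicate 1, 655 without KO_week3 replicate 2, 193 without KO_week3 replicate 4, 683 without WT_week3 replicate 2 and 260 without WT_week4 replicate 4. Between weeks 3 and 2 they are 292 without KO_week2 replicate 1, 444 without WT_week2 replicate 1 and 289 without WT_week2 replicate 3. Between weeks 4 and 2, leaving out the same libraries gives 524, 537 and 434.

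Wild-type tumours differed widely from wild-type culture. C3, the central complement protein, rose from 0.242 ± 0.0717 CPM in culture to 545 ± 139 CPM at week 4 (log2 11.09, SE 0.42, adjusted p = 5.8e-16), and LTB, a cytokine of the tumour necrosis factor family, to 22.6 ± 3.8 CPM at week 2 and 58.8 ± 18.5 CPM at week 3 from 0.0401 ± 0.0174 CPM. C6orf15 and KCNJ5, a potassium channel, had no read in cultured wild type and reached 88.6 ± 22.8 and 20.4 ± 11.7 CPM at week 2. ID2 and ID3, inhibitors of basic helix-loop-helix factors, fell, ID2 from 52.7 ± 16.2 to 0.521 ± 0.325 CPM at week 4 (log2 -6.66). CHD5 fell from 130 ± 19.8 to 2.47 ± 0.779 CPM (log2 -5.72). Interferon response genes rose, 28, 30 and 30 of 33 at weeks 2, 3 and 4 (medians 2.01, 3.21 and 2.86; adjusted p = 0.0307, 0.0139 and 0.0160 with an estimated correlation). So did 12, 13 and 13 of 13 genes of MHC class I presentation (medians 1.84, 2.65 and 2.58; adjusted p = 0.0152, 0.0096 and 0.0074 with an estimated correlation). By edgeR 4532 genes changed at week 2 (2176 up, 2356 down), 7193 at week 3 (3549 up, 3644 down) and 6794 at week 4 (3382 up, 3412 down). With RLE size factors more genes rise than fall at each week (2401 against 2031, 3827 against 3356 and 3600 against 3168), as with DESeq2. The week 2 count is 2558 without WT_week2 replicate 1. Reads from mouse cells, if counted in tumours, are part of these values.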

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

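The tests of neighbouring gene pairs, blocks of neighbouring genes and zinc finger genes, those of gene length and other cell types in WT_week3 replicate 2, and the motif count with zinc finger genes and blocks left out were chosen only after the results they bear on were seen.

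A knockout effect that differs between settings was found by testing the difference itself in the joint edgeR fit. That fit called 741 genes between week 2 tumours and culture, 2484 between week 3 and culture, 1741 between week 4 and culture, 686 between weeks 3 and 2, 397 between weeks 4 and 3 and 810 between weeks 4 and 2. Fitted per setting, the common biological coefficient of variation between libraries was 0.129 in culture and 0.330, 0.340 and 0.174 at weeks 2, 3 and 4. A shared estimate of the spread cannot match all of these, and the counts change with the libraries fitted, as given above. Differences of log2 effects between week 2 and culture were 5.05 for EFNA5, 4.44 for PDK4, 4.13 for KLK10, 4.09 for KIAA1244, 3.72 for DDIT4L, -10.37 for COL13A1, -6.97 for CORO2B, -6.21 for CSPG4, -6.00 for C3 and -5.43 for CX3CL1. Between week 3 and culture they were 7.35 for TNS4, 6.85 for AFAP1L2, 6.85 for KLK10, 5.92 for IGFBP4, 5.90 for EFNA5, -11.92 for DENND2A, -9.14 for CORO2B, -6.77 for ITPKB, -6.42 for FAM65C and -5.82 for TENM2. Between week 4 and culture they were 6.06 for PPAP2B, 6.03 for AFAP1L2, 5.73 for TNC, 5.70 for TNS4, 5.64 for KLK13, -10.12 for DENND2A, -7.12 for CORO2B, -6.55 for TENM2, -6.06 for FAM65C and -5.83 for ITPKB. Between weeks 3 and 2 they were 7.19 for COL13A1, 5.92 for LAMB3, 5.68 for FAT2, 5.23 for AFAP1L2, 4.83 for SDK1, -6.23 for TPD52L1, -3.63 for IL12A, -3.55 for CORO6, -2.95 for AMT and -2.89 for ADM. Between weeks 4 and 3 they were 9.71 for MMP3, 6.21 for COL3A1, 5.84 for PTX3, 3.77 for KLRC2, 3.69 for HSPA6, -4.22 for BCHE, -3.21 for ABCG1, -3.13 for ANKEF1, -2.57 for TTYH1 and -2.20 for PRODH. Between weeks 4 and 2 they were 9.12 for COL13A1, 6.94 for AHR, 6.35 for LAMB3, 6.07 for GULP1, 5.97 for TNC, -3.86 for TPD52L1, -3.65 for ALDH8A1, -2.69 for DEPDC7, -2.60 for MATN2 and -2.59 for CCDC80. Values of COL13A1, DENND2A, KLK13, AHR and GULP1, of TPD52L1 between weeks 3 and 2, and of COL3A1, PTX3 and BCHE rest on groups with at most 3 reads, so their size depends on the prior count.

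A library far from the other 3 of its group was found 15 times among 135 groups of 4. For normal values the test finds about 1 in 20 by chance, or 6.75. Where the other libraries are at 0, any read is flagged, so that rate does not hold and the excess is not a result. In KO_cell_line, the pancreatic acinar list was 2.84 CPM in replicate 3 (others 1.73 to 1.77), PTX3 0.0279 CPM in replicate 2, EFNA5 0.195 CPM in replicate 2 and PNMAL1 0.0585 CPM in replicate 3 (the other libraries 0 for these genes). In WT_cell_line, ZNF608 was 1.39 CPM in replicate 4, CX3CL1 1.61 CPM in replicate 1 and PTPRZ1 22.8 CPM in replicate 1. In WT_week3, KLK13 was 0.243 CPM in replicate 3 and CPA4 0.362 CPM in replicate 1 (the other libraries 0 for both). In WT_week4, KLK13 was 0.0817 CPM in replicate 3 and NOX3 0.0379 CPM in replicate 4 (the other libraries 0 for both). There SNCG was 2.65 CPM in replicate 2 (others 0.367 to 0.417) and CPA4 0.617 CPM in replicate 2. In KO_week4, TNC was 54.8 CPM in replicate 4 (others 5.03 to 12.6) and DENND2A 0.0375 CPM in replicate 3 (others 0).

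Other splits of the same libraries were fitted for each comparison with at least 3 libraries per group. The real split alone (1 of 35) gave as many genes in culture (5737, highest other 0), at week 3 (3268, highest other 508) and at week 4 (6536, highest other 0). So it did for wild type against culture at week 3 (7193, highest other 795) and week 4 (6794, highest other 1). The other splits mix genotypes, or tumour with culture, which widens the spread within groups and lowers their counts. The groups of samples therefore differ, but this test does not tell genotype from other differences between them. For differences between effects, libraries were moved between settings within a genotype. As many genes came from 1 of 50 splits for week 3 against culture (2484, highest other 2086), 2 of 50 for week 4 against culture (1741, highest other 5381) and 2 of 50 for week 4 against week 3 (397, highest other 403), counting the real split. Each share is under 0.05, but the 5381 genes of another split, which moves 4 knockout libraries and 1 wild-type library, point to a structure of the samples: moving libraries unevenly lets differences between settings enter. Comparisons with week 2, with 2 libraries per group, were not tested this way.

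The first pattern weighed is the 364 genes changed at least 2-fold the same way in all 4 settings (116 higher, 248 lower). Of those placed on the genome, 42% had a next expressed gene changed the same way in culture, more than in any shuffle (28.2% on average and 33.6% at most). By the bounds fixed beforehand this leaves loss or gain of chromosome segments undecided. The shuffles moved only the other genes and kept the 364 in place, so neighbours among the 364 count in every shuffle. The mean of the shuffles is therefore not the level that scattered genes would give. Neighbouring pairs among all genes numbered 301 against at most 113 in 1000 shuffles (permutation p = 0.001). A total of 9 blocks of 25 neighbouring genes, on chromosomes 3, 4, 19 and X, lay lower in all 4 settings, with culture medians from -1.95 to -0.77 against at most 0.73 in size in 100 shuffles, and held 50 of the 248 genes that fell. The 3' UTRs of genes that fell carry 1.22 times the ATTTA motifs of matched genes (7.47 against 6.13, permutation p = 0.001, 223 genes), a value HuR acting through AU-rich elements would need, while those of genes that rose carry 1.01 times (permutation p = 0.46). The number of knockout clones is not in the labels, so differences between clones and loss of HuR cannot be told apart.

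The second pattern is WT_week3 replicate 2, which lies apart from the other wild-type libraries of week 3. Of the genes changed in all settings, 4.67% (17 of 364) lie nearer the knockout mean. These genes were called with this library counted as wild type, so a low share is partly built in. ELAVL1, the deleted gene, stood at 140 unscaled CPM there, against 76.2 to 95.3 CPM in the week 3 knockouts. That value argues against a knockout sample under its label. Cells of other types stay open: their listed genes sum to 1213 CPM there against 1704 to 2342 CPM in the others, but to 1584 CPM on average in cultured wild type, a level that would hide a small share of such cells, and the erythroid (1.09 CPM) and pancreatic acinar (3.59 CPM) sums are the highest of the group. Gene length stays open as well: the deviation of this library has a Spearman correlation of -0.503 with gene length, against 0.389, -0.252 and -0.166 for the others. In the first run each library was set against the mean of all its companions, which gave 0.522 for replicate 1 and a verdict against length; the comparator was changed after that value was seen. No biological explanation was tested, as the labels give none.

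The third pattern is the higher mitochondrially encoded and ribosomal protein RNA of week 2 knockout tumours. Gene length as the whole cause is argued against, since with the length trend taken out the medians are 0.94 and 0.267 (before 1.16 and 0.377). With mitochondrially encoded genes left out, the ribosomal protein median is 0.366. TMM scaling already allows for most of a shift in the share of mitochondrial reads. That median could therefore hardly move, and this test cannot decide whether the share matters. The state of the RNA, the share of living cells and the genotype stay open, with 2 libraries per group. A mitochondrial share of this size also occurred without the knockout: WT_week3 replicate 2 had 8.84%, against 10.1% and 8.74% in the week 2 knockouts. The state of the RNA was not tested in either case.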

How the results depend on the processing

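The overlap of calls under DESeq2, the replicate block and the joint fit was chosen only after the data were seen; all other alternatives were fixed earlier. No call of a named gene or list reversed. Of 6878 repeats of named genes, called or not, 6633 left the status as it was, 231 ended a call and 14 gave a new one. Of 1180 repeats of lists, called or not, 1073 left it as it was, 66 ended a call and 41 gave a new one. RLE size factors changed no call of a named gene (475 repeats) or list (110). Requiring at least 2-fold, which removes smaller changes by construction, gives 1503 (501 higher, 1002 lower), 1260, 1945 and 2026 genes from culture to week 4, and 116 and 248 shared by all 4. The joint fit gives 3340, 3521 and 6062 in culture and at weeks 2 and 3, and the block 3339 and 1740 at weeks 2 and 3. Whether replicate numbers pair the samples is not settled: a sample correlated best with its own number in 1 of 4, 2 of 2, 1 of 3 and 0 of 4 cases from culture to week 4, and with 2 libraries per group either both match or neither. Differences of effects under DESeq2 number 1209 (519 positive, 690 negative) for week 2 against culture, 1180 for week 3 against 2, 716 for week 4 against 3 and 1307 for week 4 against 2. With only the groups of the contrast they number 2142 (948 positive, 1194 negative), 9 (6 positive, 3 negative), 192 and 1189 (768 positive, 421 negative), with 2170 for week 3 and 3509 for week 4 against culture. Called lists fall to 0 in every comparison of knockout with wild type by camera with an estimated correlation (1 in each at an unadjusted p under 0.05), and fry calls 11, 0, 11 and 14 from culture to week 4 (9 at week 2 at an unadjusted p under 0.05). Leaving out 1 library gives ELAVL1 at week 2 as -0.95 to -0.75, calls at week 3 as 1925 to 5460 and called lists in culture as 1 to 4. Differences then run from 376 to 735 (week 2 against culture), 289 to 927 (week 3 against 2), 193 to 683 (week 4 against 3) and 434 to 706 (week 4 against 2), and wild type at week 2 against culture from 2558 to 4230. For those a group of 2 leaves 1 sample, assumed to vary like the others. The split of week 3 against 2 turns from 385 positive and 301 negative to 241 and 295 without KO_week3 replicate 2 to 308 and 373 without KO_week3 replicate 1 and to 233 and 270 without KO_week3 replicate 4. That of week 4 against culture turns from 927 and 814 to 780 and 791 without KO_week4 replicate 2, and that of week 3 against culture from 1146 and 1338 to 1365 and 1329 with a mean of at least 1 CPM. The splits of wild-type tumours against culture turn under RLE size factors, DESeq2 and some libraries left out, so which direction has more genes is not settled there. Where not given by construction, the cause was not tested. The pseudocount alternative for normalized values was not run, since the files hold counts. Depth differs by 1.57-fold between libraries, and genes with few reads give only bounds.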

Other observations

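The counts of kallikreins and of runs of neighbouring genes, the zinc finger test and the motif count without zinc finger genes and blocks are tests chosen only after the results were seen.

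Most tested kallikreins, a family of secreted serine proteases encoded side by side on chromosome 19, rose in knockouts in each setting. All 6 tested KLK genes rose in culture, 6 of 8 at week 2, 7 of 7 at week 3 and 8 of 8 at week 4, and none fell by edgeR. In week 4 tumours KLK10 was 132 ± 22.8 against 0.497 ± 0.318 CPM and LAMB3, a laminin chain, 87.8 ± 20.8 against 9.19 ± 1.4 CPM (SD, n = 4 and 4). Among other runs of neighbouring genes that moved at least 2-fold together in culture, APOBEC3C to CBX7 on chromosome 22, 7 genes, were higher. VEPH1, PTX3, C3orf55, SHOX2, RSRC1 and MLF1 on chromosome 3 were lower. Most runs were lower, several of them of ZNF genes on chromosome 19.

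In wild-type tumours, genes of cell division fell against culture as immune genes rose. Of 28 mitosis genes 25, 24 and 26 fell at weeks 2, 3 and 4 (medians -0.83, -0.93 and -1.05; adjusted p = 0.101, 0.109 and 0.0641 with an estimated correlation), and of 30 DNA replication genes 21, 23 and 25 (medians -0.74, -0.77 and -0.85; adjusted p = 0.101, 0.116 and 0.0794 with an estimated correlation). Of 25 NF-kB and cytokine genes 14, 23 and 22 rose (medians 1.51, 2.90 and 2.57; adjusted p = 0.135, 0.0395 and 0.0527 with an estimated correlation). Of 24 hypoxia response genes 18, 20 and 19 rose (medians 1.08, 1.59 and 1.11; adjusted p = 0.116, 0.116 and 0.214 with an estimated correlation). In week 4 knockout tumours 6 of 23 NF-kB and cytokine genes rose and 7 fell (median -0.30, camera adjusted p = 0.896). Among those that rose, the cytokines LIF (195 ± 8.94 against 87.6 ± 16.4 CPM) and CXCL5 (681 ± 85.6 against 299 ± 62.2 CPM) were higher than in wild type, as was the protease MMP9 of the reported HuR targets (24.6 ± 5.94 against 1.75 ± 0.403 CPM).

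Of 409 zinc finger (ZNF) genes, 30 were lower in all 4 settings, of which 23 lie on chromosome 19, and 6 were higher. The odds ratio against other genes is 1.63, but 0.8 (interval 0.407 to 1.43) with the 9 blocks left out, which removes genes chosen for falling. Shifts of the calls along the genome, which keep neighbours together, gave as many often enough (permutation p = 0.082) that ZNF genes as a class cannot be told from the blocks they lie in. With ZNF genes and the 9 blocks left out, the motif ratio of the genes that fell is 1.19 (permutation p = 0.0087, 167 genes).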
